A study of Mus musculus with 6 samples.

How the data were processed

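Placental RNA of 3 Adra2b knockout and 3 wild-type mice at embryonic day 10.5 was measured on 6 Affymetrix whole-genome 3′ expression arrays, with 5 µg of total RNA per array per the labels. The deposited values are linear probe set intensities that the authors made with GCRMA (a background correction and summary of probe signals to 1 value per probe set), per the submitters' processing notes, which name it for 5 of the 6 samples. Its version and any further step are not given in the sources used here. Median intensities ranged from 8.78 to 9.52 between arrays. Arrays have no read depth, and the number of arrays limits the precision. Each column was assigned to its sample by the sample's label, and groups and replicate numbers were taken from the sample titles.

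Log2 of the deposited intensities was taken with no pseudocount. The 64 control probe sets were left out of the tests, and probe sets above 4 on the log2 scale (a signal of 16) on at least 3 of the 6 arrays were tested, which removed 26479 and left 18558. Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. Only probe sets with 1 symbol were named, and 0 symbols were updated. A gene was represented by its tested probe set of highest mean, which gave 10081 genes. Gene order came from a mouse RefSeq table of the GRCm38.p6 assembly, and no coordinates were taken from it because the array values name no build.

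Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were compared with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 17 lists with at least 5 measured genes of 20 lists fixed. Plots were drawn with matplotlib 3.10.9. The groups, tests, gene lists, rule for named genes and the settings varied were chosen before the data were examined. Some lists share genes: 8 of 14 measured prolactin family hormones, 7 of 16 giant cell markers, 6 of 27 spongiotrophoblast and glycogen cell markers, 6 of 29 genes of the VEGF and angiopoietin system and 4 of 21 decidual markers stand in another tested list as well.

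The genes named were, first, Adra2b and Flt1. Second came the genes past the threshold with the largest change in each direction or, where under 5 passed, the 10 with the smallest p in each direction, which was the case here. These were followed by up to 4 measured members of each tested list with the smallest p. All 3 measured embryonic neural genes and both measured sex-linked transcripts, whose lists were not tested, were named outside this rule after their values were seen. Other genes outside it are named as chosen in that way where they appear.

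The settings varied were no filter, a filter on a mean above 6, a further quantile normalization, centring each array on its median, eBayes with trend and robust settings, the replicate number as a block, leaving out each array in turn, a test without moderation of variances, camera with an estimated correlation, fry in place of camera, the mean of a gene's probe sets, and other windows around Adra2b. Array weights, the beta-actin 3′ to 5′ log2 ratio as a covariate, and the windows without knockout array 3 were added after seeing the data. The labels give no processing batch or date, so batches were not examined.

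The fits were tested on simulated data with 18558 probe sets, 200 of them changed. With 3 and 3 arrays, limma recovered 43% of the changes of 1 and 91% of those of 2 on the log2 scale, with 6 unchanged probe sets among 140 calls. Without knockout array 3 it recovered 80% and 100%, with 5 unchanged among 185. Both simulations drew independent noise with the same spread on every array, and the latter took its spread from the fit without that array. They hold no deviant array and no difference shared by many probe sets. Their rates of recovery and of false calls therefore do not carry over to the real arrays. A list shifted by 0.5 among 10081 genes with independent noise was found by camera in 20 of 20 runs, with 4 calls in 320 tests of unshifted lists. Estimated correlations within the real lists reached 0.62 (mesenchyme and smooth muscle genes), so this rate of false calls does not carry over to them.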

Results

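Expression was measured in mouse placentae at embryonic day 10.5 from animals lacking Adra2b, the gene of the alpha-2B adrenergic receptor (a G-protein-coupled receptor for noradrenaline and adrenaline), and from wild-type animals. There were 3 knockout and 3 wild-type arrays, from 3 knockout and 3 wild-type mice per the series' design text, and whether placentae were pooled is not given in the sources used here. Each array was an Affymetrix whole-genome 3′ expression array with 45101 probe sets, and the deposited values were linear signals between 2.12 and 45950. Median signals ranged from 8.78 to 9.52 between arrays. The number of arrays per group limits the precision, and an exact permutation test of 3 against 3 cannot go below p = 0.1. Differences are given on the log2 scale, knockout minus wild type, and errors are SDs over n = 3 arrays unless named as SE. The question was which placental transcripts differ without the receptor, and the study is known to have followed Flt1, the VEGF receptor whose soluble form binds VEGF.

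Adra2b itself was not analysed here, because the probe annotation lists 0 probe sets under its symbol, so the deleted gene could not serve as a check of the labels. Of the other adrenergic receptors, Adra1b and Adra2c had 5 probe sets. Their highest log2 signal on any array was 2.92, which is below the filter at 4, and so no receptor was compared.

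Signals of Ghrh, Hsd11b2 and Gjb2 were 2.19- to 3.40-fold higher in the knockout, and those of Htra1 and Rimklb were 5.95- and 8.22-fold lower. In each case all 3 knockout arrays lay on one side of all 3 wild-type arrays. These genes were chosen by small p on the same arrays, which favours such separation. No probe set passed an adjusted p of 0.05 in limma's moderated test (0 of 18558; smallest adjusted p = 0.26). At an unadjusted p under 0.05 there were 1317 probe sets, 534 higher and 783 lower in the knockout, against about 928 by chance. After a further quantile normalization the split was 718 higher and 654 lower, so the direction of the majority depends on the scaling. The excess over chance depends on single arrays. At an unadjusted p under 0.05 the count was 610, 771 and 4893 without knockout arrays 1, 2 and 3. It was 1117, 907 and 827 without wild-type arrays 1, 2 and 3. The groups did not overlap for 12.7% of probe sets, where chance gives 10%. Without knockout array 3, 881 probe sets passed, 507 higher and 374 lower, and 444 of them differed at least 2-fold.

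Knockout array 3 stood apart from knockout arrays 1 and 2, with the wild-type arrays between them on the first principal component. On the first principal component, which held 55.3% of the variance of the log2 signals, it lay at 55.8, knockout arrays 1 and 2 lay at -46.2 and -43.8, and the wild-type arrays lay between 2.02 and 18.2. Across the 18558 tested probe sets, which are not independent replicates, knockout arrays 1 and 2 correlated at r = 0.994, and knockout array 3 correlated with them at 0.945 and 0.946 and with the wild-type arrays at 0.968 to 0.973. Knockout arrays 1 and 2 correlated with the wild-type arrays at 0.964 to 0.979. These values do not show whether knockout array 3 or knockout arrays 1 and 2 are the unusual ones. The beta-actin control probe sets of knockout array 3 had a 3′ to 5′ signal ratio of 3.21, against 1.69 to 2.48 on the other arrays. Its Gapdh ratio was 1.31, against 0.893 to 1.06. The 18S rRNA control signal was 3188 on this array, 711 on wild-type array 1 and between 80.1 and 129 on the other arrays.

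**Figure D1:**
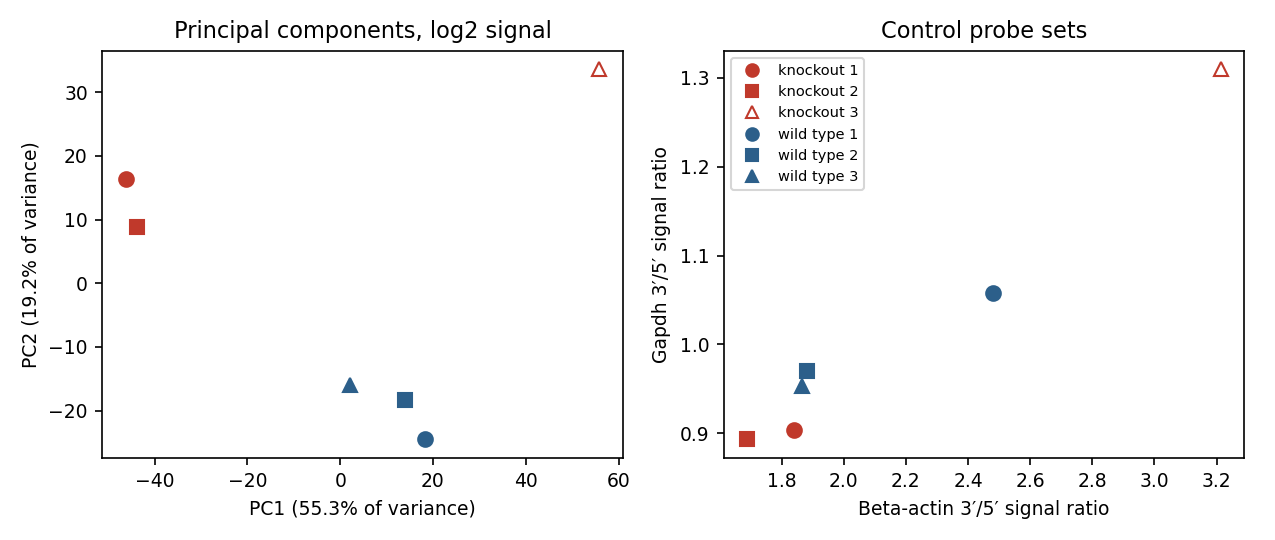
Left, the first 2 principal components of the log2 signals of the tested probe sets, in log2 units, with 1 point per array. Right, the 3′ to 5′ signal ratios (linear, no unit) of the beta-actin and Gapdh control probe sets. Knockout array 3 (open triangle) has the highest value on both components and both ratios, at 3.21 for beta-actin and 1.31 for Gapdh.

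The 10 genes with the smallest p among those with higher knockout signal differed by 1.01 to 1.76 on the log2 scale. Gjb2, the gap junction protein connexin 26 of the mouse syncytiotrophoblast, had a log2 signal of 11.82 ± 0.10 in the knockout and 10.67 ± 0.32 in the wild type, a 2.23-fold higher level. Slc16a3, a monocarboxylate transporter of the lactate-exporting type, was at 6.53 ± 0.14 against 5.38 ± 0.26. Hsd11b2, which inactivates glucocorticoids, was at 8.20 ± 0.06 against 7.07 ± 0.15, a 2.19-fold higher level. Ghrh, growth hormone-releasing hormone, showed the largest of these differences, 8.69 ± 0.31 against 6.93 ± 0.18, or 3.40-fold. Septin4 (1.57, SE 0.19), 1700011M02Rik (1.69, SE 0.21), Plbd1 (1.08, SE 0.13), Adgra3 (1.06, SE 0.15), Ptprf (1.14, SE 0.17) and Acvr2b, an activin receptor (1.01, SE 0.16), completed the group. None of the 10 passed the threshold in limma (adjusted p between 0.26 and 0.30), and all 10 passed it without knockout array 3. The latter count is no independent support, since the genes were picked on arrays that this fit reuses. Over all 10081 genes, 435 passed without that array.

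The 10 genes with the smallest p among those with lower knockout signal differed by -1.13 to -4.33. Htra1, a secreted serine protease, had a log2 signal of 8.36 ± 0.44 in the knockout and 10.93 ± 0.63 in the wild type, a 5.95-fold lower level. Adamts5, a matrix-degrading metalloprotease, was at 7.11 ± 0.26 against 8.40 ± 0.26. Rimklb, an amino acid ligase, was at 5.65 ± 0.33 against 8.69 ± 0.44, and its 4 probe sets all had lower knockout means. The small proline-rich protein Sprr2h (-4.33, SE 0.46), the metallothionein Mt4 (-2.75, SE 0.36), Prr9 (-2.23, SE 0.32) and the small heat shock protein Hspb7 (-3.16, SE 0.43) were each more than 4-fold lower. Coch (-2.32, SE 0.33), Shisa3 (-1.62, SE 0.25) and the nuclear receptor Rorb (-1.13, SE 0.17) were the others. None of the 10 passed the threshold in limma (adjusted p between 0.26 and 0.28), and all 10 passed it without knockout array 3. This last count is no independent support either, for the same reason, with 435 of all 10081 genes passing in that fit. The knockout means of Sprr2h, Hspb7 and Coch lay below the filter level, where signals are compressed, and the Sprr2h probe set can also detect related Sprr2 transcripts.

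**Figure D2:**
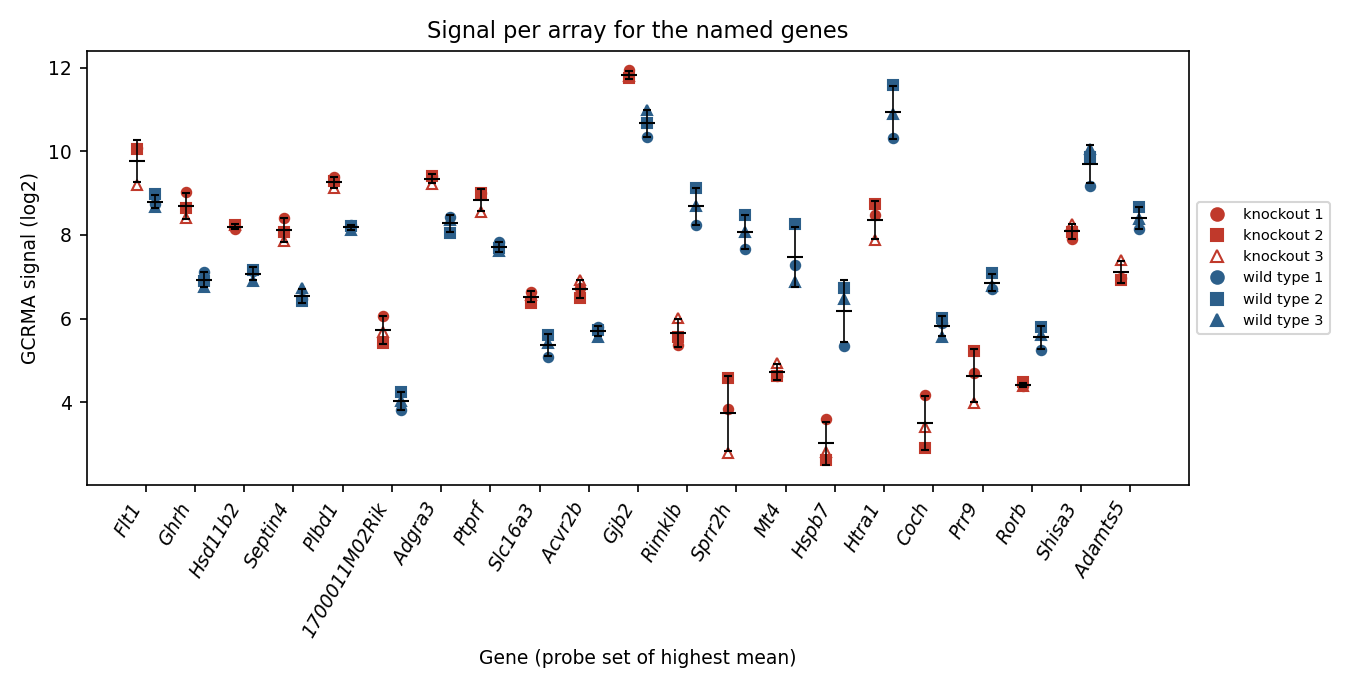
Log2 signal of Flt1 and the 20 named genes on each array, with symbols for the replicate number, knockout in red and wild type in blue; black bars are the mean ± SD of 3 arrays. In each of the 21 genes the 3 knockout values lie on one side of the 3 wild-type values, as for Htra1 at 7.87 to 8.74 against 10.3 to 11.6. The 20 genes were chosen by small p on these same arrays, which favours such separation.

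Flt1 signal was higher in the knockout. Its probe set of highest mean gave 9.77 ± 0.51 in the knockout and 8.80 ± 0.16 in the wild type, a log2 difference of 0.97 (SE 0.27) or 1.96-fold, and all 3 knockout values exceeded all 3 wild-type values. The other 3 Flt1 probe sets gave 0.86, 0.88 and 0.89, and in those at 0.86 and 0.89 the groups overlapped, because knockout array 3 lay within the wild-type range. The difference did not pass the threshold in limma (adjusted p = 0.63), and without knockout array 3 it was 1.26 with an adjusted p of 0.019. With array weights, chosen after seeing the data, it was 1.24 with an adjusted p of 0.015. Flt1 is also 1 of the 27 measured members of the spongiotrophoblast and glycogen cell list, whose median difference was 0.71, and like that list it was higher on knockout arrays 1 and 2 (10.07 and 10.04) than on knockout array 3 (9.18). The array does not tell the soluble from the membrane-bound form here, since the position of each probe set in the transcript was not available to the comparison.

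Of the other 28 measured genes of the VEGF and angiopoietin system, none passed, either over all genes or adjusted over the list alone (0 of 29). Angpt2, a vessel-destabilizing ligand, had a difference of -0.27 (SE 0.14), its receptor Tek -0.35 (SE 0.19) and the hypoxia-inducible factor Epas1 -0.20 (SE 0.12). The list as a whole was not shifted in limma's camera test with the preset inter-gene correlation of 0.01 (20 of 29 members lower, adjusted p = 0.20). It was shifted downward without knockout array 3 (adjusted p = 0.0032), with array weights (0.0037) and without the filter on dim probe sets (0.022). The endothelial marker list fell (17 of 23 members lower, median -0.20, adjusted p = 0.020; adjusted p = 0.52 with an estimated correlation). Its 4 members with the smallest p were Emcn (-0.40, SE 0.20), Tek, Sox17 (-0.29, SE 0.16) and Cldn5 (-0.38, SE 0.24), and 0 of 23 passed over all genes or adjusted over the list alone. Relative to the wild-type mean, the endothelial medians were -0.35, -0.18 and 0.08 on the knockout arrays and -0.18, 0.02 and 0.15 on the wild-type arrays. Knockout arrays 2 and 3 thus lay within the wild-type range, and only knockout array 1 lay below it. The shift was lost without knockout array 1 (adjusted p = 0.64), knockout array 2 (0.068), wild-type array 2 (0.11) or wild-type array 3 (0.22).

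Marker genes of the trophoblast lineages were shifted upward in the knockout as groups. Of the 27 measured spongiotrophoblast and glycogen cell markers, 24 were higher (median 0.71, camera adjusted p = 4.9e-07; adjusted p = 0.49 with an estimated correlation). No member passed over all genes, and 3 passed adjusted over the list alone. Tpbpb, a spongiotrophoblast-specific transcript, rose by 1.58 (SE 0.35), and Psg23, a pregnancy-specific glycoprotein, by 0.52 (SE 0.12), while Htra1 fell by 2.57. Trophoblast giant cell markers (11 of 16 higher, median 0.22, adjusted p = 0.0041; adjusted p = 0.49 with an estimated correlation) had 3 members past the threshold adjusted over the list alone and 0 over all genes. These were Prl7a2, a prolactin-family hormone (2.04, SE 0.40), and the placental cathepsins Ctsq (1.49, SE 0.39) and Cts8 (0.68, SE 0.16), and the matrix protease Mmp9 had a difference of 0.63 (SE 0.20). Placental cathepsins (7 of 9 higher, median 0.68, adjusted p = 0.0021; adjusted p = 0.39 with an estimated correlation) had the same Ctsq and Cts8 as the 2 members past adjusted over the list alone, with Ctsr at 0.72 (SE 0.23) and Ctsm at 2.11 (SE 0.99).

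Labyrinth and syncytiotrophoblast markers were shifted upward too (15 of 22 higher, median 0.43, adjusted p = 0.00017; adjusted p = 0.39 with an estimated correlation). No member passed over all genes and 4 passed adjusted over the list alone, namely Gjb2 and Slc16a3, the protease inhibitor Spint1 (1.37, SE 0.29) and the transferrin receptor Tfrc (0.66, SE 0.17). Among 14 prolactin family hormones, 10 were higher (median 0.31, adjusted p = 0.013; adjusted p = 0.49 with an estimated correlation), and 0 passed over all genes. Adjusted over the list alone, Prl7a2, Prl2b1 (0.67, SE 0.15) and Prl6a1 (0.67, SE 0.19) rose and Prl3c1, a decidual member, fell by 3.42 (SE 0.67), with a knockout mean below the filter level. Erythroid genes were shifted upward (8 of 10 higher, median 0.47, adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation), with the embryonic globins Hbb-bh1 at 0.35 (SE 0.12) and Hba-x at 0.67 (SE 0.32), Ermap at 0.87 (SE 0.40) and Tal1 at 0.65 (SE 0.30). None of the 10 passed over all genes or adjusted over the list alone. The giant cell call was lost without wild-type array 1 (adjusted p = 0.14), the prolactin call without knockout array 3 (0.055) or wild-type array 1 (0.33) and with array weights (0.077), and the erythroid call without wild-type array 2 (0.067). Members of the Psg, Ceacam, prolactin and placental cathepsin families have closely related sequences, so their signals are uncertain where a probe set detects several of them.

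In these lists the medians were higher on knockout arrays 1 and 2 than on knockout array 3. Relative to the wild-type mean, the median spongiotrophoblast marker lay at 1.28 and 1.16 on these arrays and at -0.01 on knockout array 3. The corresponding labyrinth medians were 0.58, 0.53 and 0.14, against at most 0.11 on a wild-type array, those of the giant cell markers 0.50, 0.35 and -0.03, those of the cathepsins 0.62, 0.80 and 0.02, those of the prolactin family 0.41, 0.43 and 0.02, and those of the erythroid genes 0.63, 0.54 and -0.04. Single members were as high on knockout array 3 as on the other knockout arrays, among them Gjb2 (11.80 against 11.93 and 11.74) and Prl6a1 (13.48 against 13.30 and 13.43).

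**Figure D3:**
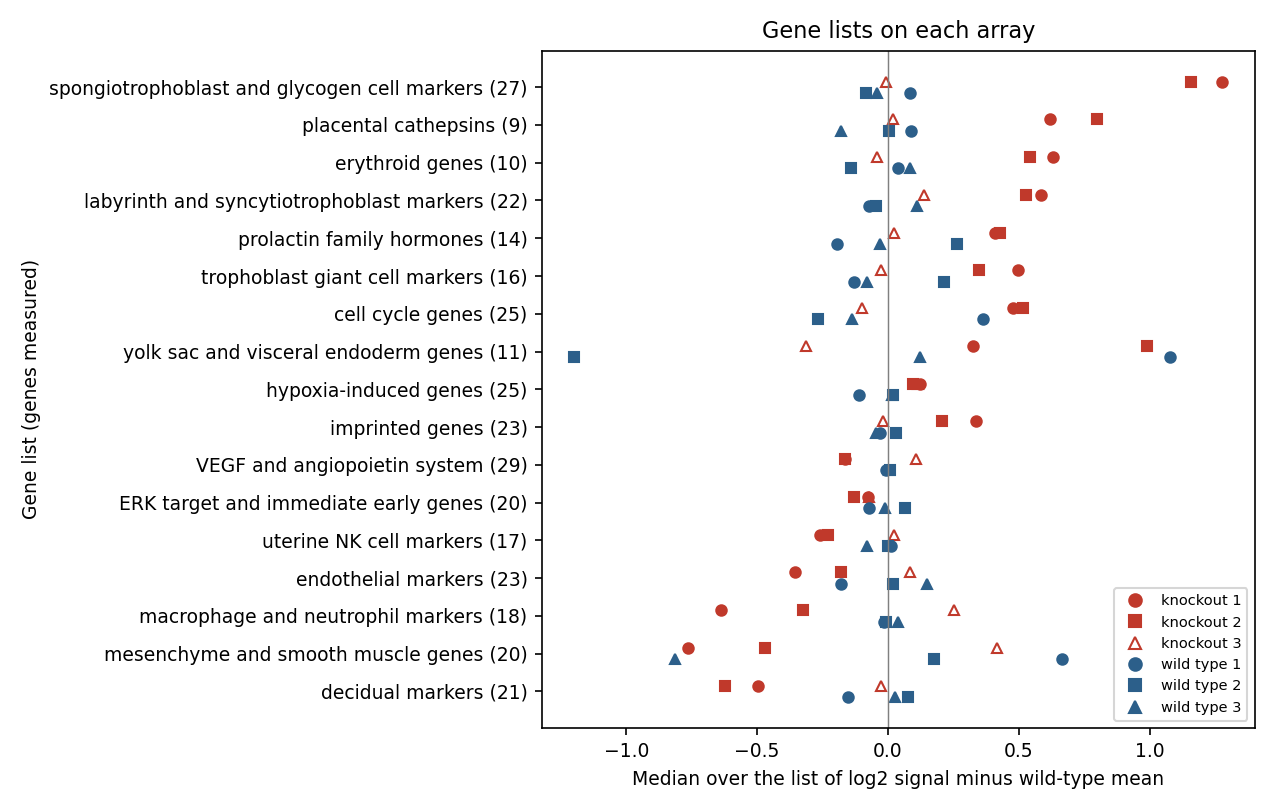
Median over each gene list (number of measured genes in brackets) of the log2 signal minus the wild-type mean, 1 point per array, knockout in red and wild type in blue. Knockout arrays 1 and 2 lie to the right for the trophoblast lists and to the left for the decidual list, while knockout array 3 (open triangle) lies near the wild-type arrays, at -0.01 for spongiotrophoblast and glycogen cell markers and -0.03 for decidual markers.

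Marker lists assigned to maternal cell types were shifted downward in the knockout, though the maternal or embryonic origin of these transcripts was not measured. Of 21 decidual markers, 19 were lower (median -0.28, camera adjusted p = 0.00012; adjusted p = 0.49 with an estimated correlation). Over all genes 0 members passed, and 2 passed adjusted over the list alone, Prl3c1 and Erv3 (-1.10, SE 0.22). The decidual hormone Prl8a2 had a difference of -0.37 (SE 0.12) and Hoxa11, a uterine patterning factor, -0.53 (SE 0.18). Uterine NK cell markers were lower in 13 of 17 (median -0.14, adjusted p = 0.010; adjusted p = 0.49 with an estimated correlation). Their members with the smallest p were Nkg7 (-0.39, SE 0.13), Prf1, which encodes perforin (-0.31, SE 0.13), Ctsw (-0.40, SE 0.18) and Eomes (-0.42, SE 0.23), and 0 of 17 passed over all genes or adjusted over the list alone. Macrophage and neutrophil markers were lower in 14 of 18 (median -0.24, adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation). Lcn2, lipocalin 2 (-0.73, SE 0.14), was the 1 member past the threshold adjusted over the list alone, 0 passed over all genes, and Fcer1g (-0.40, SE 0.12), Cd14 (-0.60, SE 0.30) and C1qb (-0.59, SE 0.35) did not pass. The NK call was lost without knockout array 1 (adjusted p = 0.24) or 2 (0.15), and the macrophage call without knockout array 1 (0.58), knockout array 2 (0.084) or wild-type array 2 (0.067). Relative to the wild-type mean, the decidual medians were -0.50 and -0.62 on knockout arrays 1 and 2 and -0.03 on knockout array 3, the NK medians were -0.26, -0.23 and 0.02, and the macrophage medians were -0.64, -0.32 and 0.25.

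Hypoxia-induced genes were shifted upward (17 of 25 higher, median 0.11, adjusted p = 0.036; adjusted p = 0.39 with an estimated correlation). Higd1a (0.54, SE 0.14), Ak4 (0.83, SE 0.29), the glucose transporter Slc2a1 (0.44, SE 0.16) and Ero1a (0.42, SE 0.17) had the smallest p, and 0 of 25 passed over all genes or adjusted over the list alone. That call was lost without knockout array 3 (adjusted p = 0.58), without wild-type array 1 (0.33), without the filter (0.14), with the stricter filter (0.12) and after a further quantile normalization (0.076), with array weights (0.61) and with the beta-actin ratio as a covariate (0.094), the last 2 chosen after seeing the data. Cell cycle genes were shifted upward (22 of 25 higher, median 0.20, adjusted p = 0.031; adjusted p = 0.60 with an estimated correlation), with Ccnb2 at 0.55 (SE 0.28), Ccne1 at 0.33 (SE 0.17), Mcm7 at 0.36 (SE 0.19) and Rrm1 at -0.30 (SE 0.16). The cell cycle medians were 0.48, 0.52 and -0.10 on the knockout arrays and 0.36, -0.27 and -0.14 on the wild-type arrays, and the hypoxia medians were 0.12, 0.10 and 0.12 against -0.11, 0.02 and 0.02. None of the 25 passed over all genes or adjusted over the list alone, and the call was lost without knockout array 1 (adjusted p = 0.22), knockout array 2 (0.20), wild-type array 2 (0.52) or wild-type array 3 (0.078), without the filter (0.19), and with the mean of a gene's probe sets (0.078).

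The remaining lists were not shifted with all 6 arrays, and 0 of their members passed over all genes or adjusted over the list alone. Among 23 imprinted genes (adjusted p = 0.16), Dlk1, a Notch-family ligand, had a difference of 1.08 (SE 0.22), Slc22a18 0.75 (SE 0.28), the creatine-synthesis enzyme Gatm -0.50 (SE 0.12) and Osbpl5 -0.45 (SE 0.13). Among 20 ERK target and immediate early genes (adjusted p = 0.14; 0.011, downward, without wild-type array 1), Atf3 had a difference of 0.33 (SE 0.15), Egr1 -0.30 (SE 0.20), Ccn1 -0.55 (SE 0.37) and the ERK-pathway inhibitor Spry2 -0.88 (SE 0.53). Mesenchyme and smooth muscle genes (adjusted p = 0.20) included Pdgfrb at 0.32 (SE 0.15), Fn1 at 0.56 (SE 0.26), Pdgfra at -0.26 (SE 0.20) and Col1a2 at -0.58 (SE 0.52). That list was shifted downward without knockout array 3 (adjusted p = 0.0022) or wild-type array 3 (0.00045), and with array weights or the beta-actin covariate (both 0.017). Yolk sac and visceral endoderm genes (adjusted p = 0.57) included Rbp4 at -1.07 (SE 0.49), Spink1 at 0.64 (SE 0.50), Apoa2 at 0.72 (SE 0.63) and Afp at 0.72 (SE 0.74), all with overlapping groups. Lists with under 5 measured genes were not tested. These were the adrenergic receptors with 0, the embryonic neural genes with 3, namely Tubb3 (0.54, SE 0.22), Stmn2 (-0.32, SE 0.81) and Nes (-0.08, SE 0.23), and the sex-linked transcripts with 2, namely Xist (-0.31, SE 0.57) and Eif2s3y (-0.07, SE 0.82). Xist is expressed from the inactive X chromosome of female cells, and another of its probe sets had log2 signals of 8.44, 8.61 and 11.50 on the knockout arrays and 10.72, 11.02 and 10.31 on the wild-type arrays.

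Genes next to Adra2b on chromosome 2 were examined because a targeted locus can carry flanking sequence of the strain in which it was made. None of the 50 tested genes nearest to Adra2b, 25 on each side, passed an unadjusted p of 0.01 in limma, against 156 of 10018 elsewhere (1.56%; Fisher's exact test, two-sided, p = 1). With 10 genes on each side, the count was 0 of 20. With 50 genes on each side it was 3 of 100, or 3% against 1.53% elsewhere (Fisher's exact test, two-sided, p = 0.202). At the share of 1.56% elsewhere, 0 is an ordinary count in windows of 20 or 50 genes. These counts therefore cannot show that flanking sequence has no effect. No gene passed the adjusted threshold with all 6 arrays, so the comparison at that threshold is void. Without knockout array 3, chosen after seeing the data, 0 of the 50 passed it against 435 of 10018 elsewhere (Fisher's exact test, two-sided, p = 0.278).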

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

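All tests in this part except the counts over splits of the arrays were chosen after the result was seen. No group was large enough for a test of outlying samples, because each had 3 arrays. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. In limma the real split gave 0 probe sets, and the highest of the others 0, so 10 of 10 splits were as large, for all changes and for those of at least 2-fold. For gene lists shifted in camera, the real split gave 12 and the highest other 10, and 1 of 10 splits was as large. The 3 splits that put knockout arrays 1 and 2 with a wild-type array gave 9, 10 and 10 lists, the others between 3 and 8, so the list shifts follow a structure of the samples in which these 2 arrays lie together.

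Knockout array 3 lay apart from the other knockout arrays. Lower RNA integrity or a shorter labelled product is a candidate explanation, since the beta-actin 3′ to 5′ log2 ratio was 1.684 on this array and at most 1.31 on the others. A larger share of maternal tissue on this array stays open, since 8 lists of embryonic and maternal cell types lay on the side it needs against knockout arrays 1 and 2, but 5 of the 8 did so against the wild-type mean, with medians between -0.04 and 0.25. Xist signal was 11.41 on this array and 9.82 and 9.11 on the other knockout arrays. The Y-linked Eif2s3y, at 4.66 against 3.07 and 5.41, did not set it apart. A probe set each of the Y-linked Kdm5d (2.75 against 2.54 and 4.75) and Uty (2.82 against 3.00 and 4.82), chosen after their values were seen, was raised only on knockout array 2 of these. Their other probe sets lay near or below the filter level. Neither the sex of the embryos nor another biological difference between the knockout animals was tested.

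In camera at the preset correlation, 8 lists assigned to embryonic or maternal cell types were shifted, the embryonic ones upward and the maternal ones downward. With an estimated correlation 0 of the 17 lists passed. The endothelial and mesenchyme lists were assigned to neither side and leaned downward. In them 17 of 23 and 16 of 20 members were lower (camera adjusted p = 0.020 and 0.20), so the pattern covers the assigned lists only. Knockout array 3 as the source is argued against, since in 0 of the 8 lists did its median lie further out, in the direction of the shift, than on both other knockout arrays. A larger share of embryonic tissue in the knockout dissections stays open. The 95% bootstrap intervals of the medians of 6 embryonic lists, the unshifted yolk sac list included, lay apart in 0 of 15 pairs. However, 3 of the 6 intervals lay above 0, and that of the yolk sac list ran from -0.10 to 0.72. The genes of each list were resampled and not the arrays, so these intervals leave out the spread between arrays. An effect of the genotype on the size of these tissues would give the same values and stays open, untested.

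The 10 named genes with lower knockout signal had a median difference of -2.45. Whether a smaller share of the decidua as a whole plays a part cannot be decided here. The decidual list had a median of -0.2791 (95% bootstrap interval over 10000 resamples of its 21 genes -0.38 to -0.19), and of -0.58 without knockout array 3. That interval leaves out the spread between arrays, since the knockout arrays had decidual medians of -0.50, -0.62 and -0.03. The smallest fall among the 10 genes was -1.13, but these genes were picked from all genes for small p, which favours large falls. Noise near the floor cannot be set aside for all 10 genes. In 8 of them the wild-type mean was above 6 on the log2 scale, but choosing genes by their fall favours this. Knockout means of Htra1, Shisa3 and Adamts5 were 8.36, 8.08 and 7.11, which argues against floor noise for these genes. That of Rimklb was 5.65. Those of Rorb, Prr9 and Mt4 were 4.42, 4.63 and 4.72, near the filter level, and those of Sprr2h, Hspb7 and Coch lay below it. Loss of a part of the decidua stays open, since of its 21 markers the 2 with the smallest p, Prl3c1 (-3.42, knockout mean below the filter level) and Erv3 (-1.10, among the 50 tested genes on either side of Adra2b), differed about as much as some of the 10 genes. A strain difference and an effect of the genotype stay open, untested.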

How the results depend on the processing

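The counts with array weights and with the beta-actin covariate were chosen after the data were seen. All 79 named genes kept their direction under each alternative in which they were tested, and none of the 79 passed the threshold except without knockout array 3 (33), with array weights (52) and with the beta-actin covariate (1). The number of probe sets changed in limma was 0 under the other alternatives. It ranged from 0 to 881 when 1 array was left out, and from 0 to 444 for changes of at least 2-fold, with the highest values without knockout array 3. It was 2027 and 556 with array weights, which gave that array a weight of 0.138, and 1 and 1 with the covariate (Sprr2h). The arrays that remain without knockout array 3 include a knockout pair with r = 0.994, against 0.981 to 0.989 between wild-type arrays. The Flt1 difference ranged from 0.82 to 1.26 when 1 array was left out and was 1.24 with array weights. Its adjusted p over all alternatives ranged from 0.015 to 1.00. The number of lists shifted was 12, from 8 to 12 when 1 array was left out, 0 with an estimated correlation and 0 with fry. The adjusted p of the yolk sac list was 0.864 in the reversed direction with a mean above 6. It ranged from 0.0529 to 0.776 when 1 array was left out, reversed without knockout array 2 (0.641) and wild-type array 2 (0.169). That of the mesenchyme list ranged from 0.000452 to 0.834, reversed without knockout array 1 (0.641) and wild-type array 1 (0.616). Among the 50 tested genes on each side of Adra2b, 3 (Erv3, Gatm and Spata5l1, the last chosen after its values were seen) had an unadjusted p under 0.01 (Fisher's exact test, two-sided, p = 0.202). Apart from the effect of fewer arrays or genes, the cause was not tested. With the replicate block, 0 probe sets changed (989 at an unadjusted p under 0.05, smallest adjusted p = 0.88) and 12 lists were shifted. Deviations of same-numbered arrays from their group means correlated at -0.17, -0.12 and -0.28. With 3 arrays per group and knockout array 3 apart, these values cannot show whether the numbers pair the samples. Signals near the floor limit the differences of dim genes.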

Other observations

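The genes in this part were chosen after their values were seen. Without knockout array 3, 435 genes passed the threshold in limma, 320 higher and 115 lower. Those with the largest rises included Ceacam12 (3.91), Psg21 (3.32), Ctsm (3.24), Ceacam14 (3.23) and Cts3 (3.07), members of trophoblast gene families, whose signals on knockout array 3 lay among or near the wild-type values, for Ceacam12 at 5.05 against 3.46 to 5.38. Ctse, an aspartic protease, had log2 signals of 2.79 and 4.63 on knockout arrays 1 and 2, 7.24 on knockout array 3 and 7.23 to 7.43 on the wild-type arrays. The antigen-presentation genes Cd74 (-1.44) and H2-Aa (-1.32) also fell without that array, and on it had signals of 7.88 and 9.08, above the highest wild-type values of 7.83 and 9.06.

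Of the smooth muscle and yolk sac genes, Myh11, Tagln, Apoa1 and Afp had SDs within both groups that exceeded the difference of the group means. Myh11, smooth muscle myosin, had log2 signals of 3.50, 4.43 and 6.25 on the knockout arrays and 7.29, 6.50 and 3.27 on the wild-type arrays. Tagln ran from 6.20 to 9.63 in the knockout and from 6.77 to 10.2 in the wild type. Apoa1 was at 2.85 on wild-type array 2 and at 7.57 and 6.61 on the other wild-type arrays, and Afp was at 9.61 on that array against 11.9 and 11.2.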
